A study of Sus scrofa with 9 samples.

How the data were processed

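Pig jejunal Peyer's patch tissue was held in chambers with or without immune stimulation, and RNA of all tissues of a kind was pooled into a library, per the labels. The 9 arrays compared cRNA of the normal, stimulated and subtracted libraries in 2 channels. Groups and replicate numbers were taken from the array titles, giving 2 arrays for each of 3 pairings of libraries and 3 arrays with subtracted cRNA in both channels. The dyes are not given in the sources used here.

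The deposited values are log ratios on the natural log scale, 1 per spot, as read from the values: the lowest value on the arrays, -4.605, is the natural log of 0.01, a floor that 1 to 19 spots per array reached. How the authors normalized the ratios, corrected background or filtered spots is not given in the sources used here. The array medians lay between -0.08 and 0.06 on the natural log scale and the means between -0.009 and 0.0105, so centring by the authors is plausible from the values but not stated, and the numerator stays unknown. Values were divided by the natural log of 2 to give log2 ratios, and no further normalization was applied. No intensities were used, so signal over background and dim spots could not be judged.

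Spots were grouped into probes by a print layout inferred from the annotation, in which 4 spots share a probe. All 321 named probes had all 4 spots named with 1 gene. The annotation named 1284 of 12288 spots (10.4%), for 236 genes, 230 of which matched a gene of the reference table by identifier, and no spot had several genes. The other 2751 probes are unnamed here, so their layout could not be checked by name. The 4 spots were averaged. For a gene with several probes (54 genes) each probe was tested and the one with the largest absolute mean over the pair named. Its pair mean is thus the most extreme of its gene, while its fitted value need not be. The spot median, computed first, gave more calls and is kept as an alternative chosen after seeing the data.

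The 2 arrays of a pair carry the same 2 pools and were averaged as 1 technical replicate. limma 3.58.1 in R 4.3.3 was fitted to the 3 pair means of each probe with 2 coefficients and 1 residual degree of freedom, followed by empirical Bayes moderation, and probes were called at a Benjamini-Hochberg adjusted p under 0.05. The residual is the failure of the 3 comparisons to add up, so the test compares these library preparations and p measures array error only. The named genes were fixed by rule: up to 10 highest and 10 lowest among named probes past the threshold with 1 sign on both arrays, plus up to 4 called members of each fixed list, or 2 members as values where none was called. Where fewer than 10 probes passed, 2-fold on both arrays took the place of the test. Of 24 lists fixed before the data were examined, 13 had at least 4 measured genes and were described by their median, set against 10000 random lists of the same number of named probes. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.

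The rule for the sign of a ratio departed from its wording. It was to turn an array by its channel labels where the 2 arrays of a pair correlated below 0. The normal against subtracted pair had r = 0.50 and kept the title order. The stimulated pairs had r = -0.07 and -0.06, too near 0 to tell the orders apart, and the title order was kept for them after the data were seen, because the 6 correlations among the other 4 arrays all had the signs that the titles give and 3 of 6 had those of the channels. Without the repeated grid positions, and on named probes alone, these were 5 of 6 and 2 of 6. The exception was array 2 of stimulated against normal with array 2 of normal against subtracted, at -0.22 over all probes, 0.13 without those positions and 0.12 on named probes. The same stimulated array had -0.64, -0.36 and -0.07 with array 1 of normal against subtracted on these 3 sets of probes. Correlations among array 2 of the 3 pairs have the same expected sign in the title order and with all pairs turned by channel. Only those with array 1 of normal against subtracted tell these 2 orders apart. The rule as worded turns only the stimulated pairs. Array 2 of stimulated against subtracted would then correlate below 0 with array 2 of normal against subtracted. That value was 0.49, 0.58 without the repeated grid positions and 0.76 on named probes. The exception above, at 0.13 and 0.12, has the sign of that order. Applied as worded, the rule gave 0 calls in each of the 3 comparisons. The common sign was to be read from the fibroblast, ribosomal and translation lists, which differed, so no direction is given.

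On simulated data with 3072 probes and 200 changed probes, the fit recovered 93% of 2-fold changes and 0.5% of 1.5-fold changes between normal and subtracted. It recovered 90% and 0% between stimulated and normal. Against the subtracted library, where 382 and 383 stimulated probes were changed, it recovered 95.3% and 19.3%. These shares apply only where every pair mean carries a change in full. In the data, array 1 had r = -0.06 with its partner for stimulated against normal and -0.07 for stimulated against subtracted. The simulation therefore does not give the share recovered in these data, which was not tested. Alternatives covered centring, scaling, thresholds, robust moderation, array-level fits with a dye term, and the omission of each array. Those added after seeing the data were the spot median, block centring, both channel orientations and omission of array 1 of both stimulated pairs together. The repeated grid positions were also removed from the finished calls, with no new fit or adjustment. Where an array was left out, its partner was assumed to vary like the other arrays, and a dye bias no longer cancelled in that pair. No spot was reassigned to another probe in any reported comparison.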

Results

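Pig jejunal Peyer's patch, the organised lymphoid tissue of the small intestine, was profiled on 9 spotted 2-colour arrays. Labelled cRNA came from 3 cDNA libraries. The normal library was pooled from unstimulated tissue. The stimulated library was pooled from tissue exposed to Salmonella, to cholera toxin with lipopolysaccharide, or to a phorbol ester with a cyclic AMP analogue and concanavalin A, in each case with and without the protein synthesis inhibitor cycloheximide. The subtracted library combined both and had fibroblast RNA subtracted. Each of the 3 pairings of libraries was hybridised on 2 arrays with the channels exchanged, and 3 further arrays carried subtracted cRNA in both channels. The arrays held 3072 probes of 4 spots each, of which 321 probes had a gene name, for 236 genes. Between 12220 and 12282 of the 12288 spots had a value on each array, and the number of arrays limits the precision.

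Log2 ratios are given in the order of the array titles. A value above 0 means more transcript in the first-named library only if that library was the numerator, which the labels do not state, so signs are reported without a direction. With the sign turned, every count above 0 and below 0 changes places. Each library was 1 pool, so the adjusted p-values below measure array error and say nothing of the spread between animals.

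The normal and the subtracted library differ by the subtraction and by the stimulated material in the subtracted library, which this comparison alone cannot tell apart. In their comparison, 8 named genes past the test lay below 0 and 3 above 0. The values furthest below 0 belonged to CLCA1, a secreted product of goblet cells, with a fitted log2 ratio of -1.45 (SE 0.21, limma adjusted p = 0.018), and to PGK1, a glycolytic kinase, with -1.43 (SE 0.17, adjusted p = 0.010). CTLA4, an inhibitory receptor of T cells, had -1.31 (SE 0.23) and MDH1, the cytosolic malate dehydrogenase, had -1.12 (SE 0.12). Above 0 were FABP2, the intestinal fatty acid binding protein of enterocytes, at 0.79 (SE 0.12, adjusted p = 0.019), the translation elongation factor subunit EEF1G at 0.69 (SE 0.13), and LYZ, lysozyme, at 0.68 (SE 0.12). All 11 genes had the same sign on both arrays of the pair.

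The other 4 genes below 0 were PPP1R14B, a phosphatase inhibitor, at -1.01 (SE 0.19), SPAI-2 at -0.89 (SE 0.14), the chromatin protein gene HMGB2 at -0.88 (SE 0.15) and the ribosome-associated scaffold RACK1 at -0.72 (SE 0.13). Their adjusted p-values lay between 0.025 and 0.045. Probes of 1 gene did not always behave alike. Of the 3 CLCA1 probes, another passed at -0.84 (SE 0.13) and the last had -0.14 (SE 0.12). The second FABP2 probe had 0.17 (SE 0.23) and the second LYZ probe 0.16 (SE 0.16). The further HMGB2 probes had -0.36 and -0.14, the further SPAI-2 probes 0.08 and -0.26, and the second PPP1R14B probe -0.42.

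**Figure D1:**
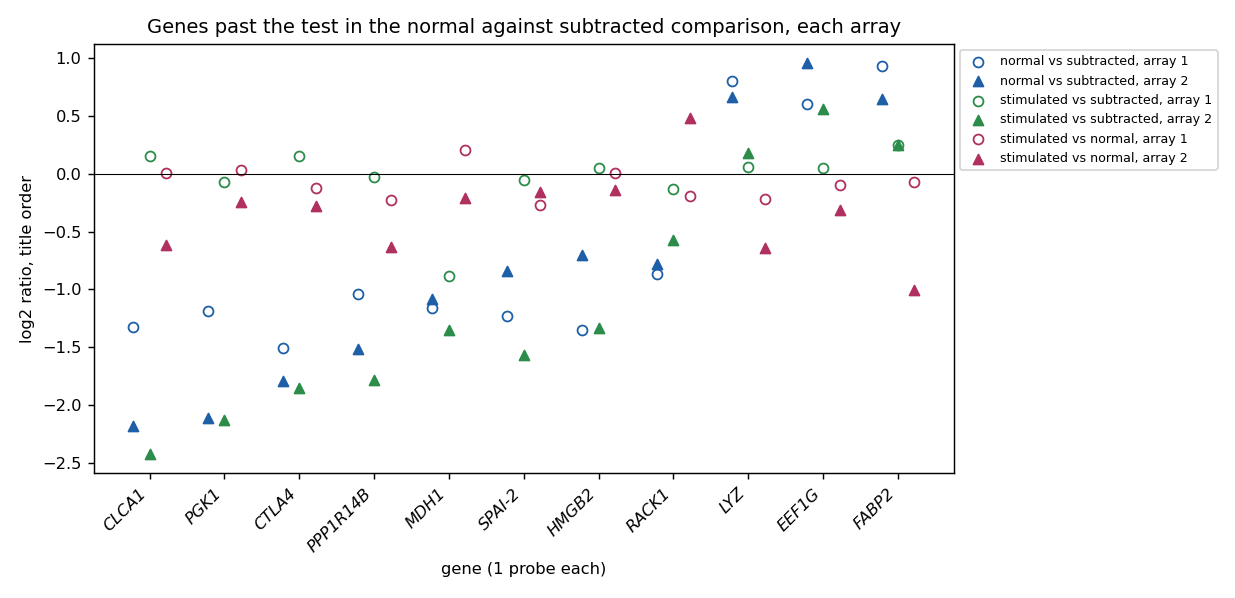
Log2 ratio in title order (vertical axis) of the 11 genes past the test in the normal against subtracted comparison (horizontal axis, 1 probe each), with 1 point for each of the 6 arrays that compare libraries. The 2 arrays of normal against subtracted lie on the same side of 0 for each gene, whereas for CLCA1 the 2 arrays of stimulated against subtracted gave 0.15 and -2.42.

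Across all 3072 probes the test called 140, of which 13 lay above 0 and 127 below 0, and 12 of these were named. At an unadjusted p under 0.05 there were 640. Of the 140 probes, 90 were unnamed and sat at 4 positions in row 1 of the probe layout that repeat in every layout block, called the repeated grid positions here. All 90 lay below 0, which left 50 elsewhere, 13 above 0 and 37 below 0. Of these 50, 12 were other probes of layout row 1, all below 0, and no probe of that row had a gene name. Outside the repeated grid positions the balance turned in the fit of 9 single arrays, with 31 above 0 and 22 below 0. It also turned, by less, when array 1 of both stimulated pairs was left out. Without array 1 of both stimulated pairs, a setting chosen after seeing the data, 465 were called, 192 above 0 and 273 below 0. By size alone, 55 probes reached 2-fold on both arrays with the same sign, 1 above 0 and 54 below 0, and 44 of the 55 sat at the repeated grid positions. The named genes among the 55 were CLCA1, CTLA4, MDH1, PGK1 and PPP1R14B. No probe did so in any of the 3 pairs that can be formed from the arrays with the same cRNA in both channels.

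Of the gene groups fixed beforehand, the translation factors had the most extreme median in this comparison, -0.34, at percentile 1.1 of random lists of the same size, but their 2 called members went opposite ways, EEF1G above 0 and RACK1 below 0. The same 2 passed when adjusted over the list alone. The 17 ribosomal protein probes had a median of 0.19, at percentile 94.3 of random lists. Of these, 13 lay above 0 and none passed, with RPL14 at 0.48 and RPS16 at 0.38. The fibroblast and matrix genes, which subtraction with fibroblast RNA would act on, had a median of 0.16 with 5 of 7 probes above 0 and none called. Their furthest members were ACTB at 0.38 and DCN, the matrix proteoglycan decorin, at 0.45. These lists were to set the direction of the ratio, and since they pointed different ways none was taken.

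The other groups lay within the central 95% of random lists, from percentile 9.7 for the myeloid markers to 84.8 for oxidative phosphorylation. Enterocyte markers had a median of 0.10 over 21 probes with only FABP2 called, and the myeloid markers had -0.07 over 6 probes with only LYZ called. Of the proliferation genes, with a median of -0.02, HMGB2 was called, and 2 probes, 1 of them above 0, passed when adjusted over the list alone. No member was called among the inflammatory cytokines (median 0.09 but -0.01 and -0.02 on the single arrays, with IL6 at -0.46 and CSF2 at 0.54 from 1.70 and -0.29 on the 2 arrays), the heat shock genes (0.11, with HSP90AA1 at 0.64 and HSP90B1 at 0.28), the interferon-stimulated genes (0.12, with OASL at 0.29) or the antigen presentation genes (0.11, with SLA-3 at 0.40 and SLA-1 at 0.38). The oxidative phosphorylation genes (0.19, with COX6C at 0.39), the T and NK cell markers (0.03, with CD4 at -0.41 and PRF1 at 0.20) and the NF-kB targets (-0.02, with PLAU at -0.53) had no call over all probes either. MMP1, also an NF-kB target, had 0.53 and 0.59 on the 2 arrays but a fitted value of -0.09 (SE 0.39), since array 1 of stimulated against subtracted gave it -2.74. Adjusted over the list alone, 1 of the NF-kB target probes and 2 of the myeloid probes passed.

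Lists with fewer than 4 measured genes were given as members only. CLCA1 was the 1 secretory epithelial marker, PGK1 the called member of the glycolytic list, and LYZ that of the antimicrobial list. The immediate early genes BTG2 and RGS2 both had -0.02. The proteasome subunits PSMB8 and PSMA4 had 0.22 and 0.21, and the apoptosis genes CASP1 and MCL1 had -0.24 and 0.17. The B cell markers CXCR4 and CD74 had -0.08 and 0.17, and the endothelial marker ENG had -0.10. Plasma cell, smooth muscle and red blood cell markers had no named probe.

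These calls depended on both arrays of the pair and on how the stimulated arrays were read: without either array of normal against subtracted, 0 probes were called by limma (559 and 505 at an unadjusted p under 0.05), and without array 2 of stimulated against normal also 0 (280). Without array 2 of stimulated against subtracted, 32 were called, none of them named. Turning the stimulated pairs by their channel labels gave 0 as well (17), and so did a fit of the 6 single arrays (667). Scaling the arrays kept 2 of the 11 genes, PGK1 and MDH1, among 97 calls of which 1 lay above 0, and median centring lost EEF1G, LYZ and PPP1R14B.

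**Figure D2:**
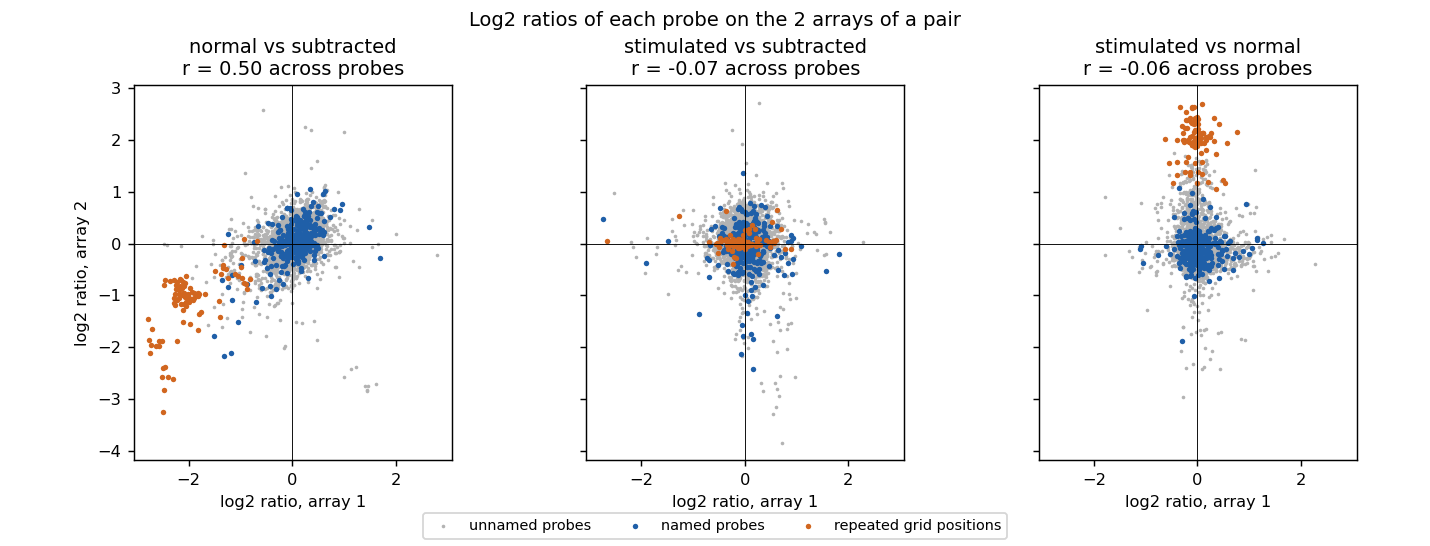
Log2 ratio in title order of each of 3072 probes on array 1 (horizontal axis) and array 2 (vertical axis) of the 3 pairs; grey points are unnamed probes, blue points named probes and orange points the 96 probes at the repeated grid positions. Only the normal against subtracted pair shows a common trend, with r = 0.50, or 0.28 without the repeated grid positions, while the stimulated pairs have r = -0.07 and -0.06.

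In the comparison of the stimulated with the subtracted library, MDH1 was the 1 named gene past the test, with a fitted log2 ratio of -1.12 (SE 0.12, limma adjusted p = 0.040) and values of -0.88 and -1.35 on the 2 arrays. Several genes that had passed in the normal against subtracted comparison were far below 0 on array 2 only. CLCA1 had 0.15 on array 1 and -2.42 on array 2, PGK1 -0.07 and -2.13, and HMGB2 0.05 and -1.34, with adjusted p-values of 0.071, 0.066 and 0.11 in that order. Outside the repeated grid positions, 11 probes were at 2-fold on both normal against subtracted arrays. All 11 kept that sign on array 2 here, and 5 did on array 1. Stimulated material in the subtracted library alone would turn the sign. The order of the stimulated pairs was itself chosen by such correlations, so these values do not settle the cause. Inflammatory genes gave IL1B at 0.57 and CXCL2 at 0.24, neither past the test, with IL1B at 1.81 on array 1 and -0.20 on array 2. The other CXCL2 probes had -0.05 and -0.13. MDH1 was not called after median centring, scaling or block centring, its adjusted p ranged from 2.1e-05 to 0.80 over the alternatives, and it fell outside the size rule that applied here and was named after its value was seen.

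In all, 7 of 3072 probes were called, all below 0 and 4 of them in layout row 1, only 3 had the same sign on both arrays, and 530 had an unadjusted p under 0.05. The sign was not uniform in other fits: the spot median gave 17 above 0 and 41 below 0, and the fit of 9 single arrays 2 and 2. Without array 1 of both stimulated pairs, calls above 0 outnumbered those below 0, but only through layout row 1. Outside the repeated grid positions that row held 134 above 0 and 25 below 0, while outside the row 225 lay above 0 and 291 below 0. No probe reached 2-fold on both arrays with the same sign. Without array 1 of this pair 92 were called, 16 of them named, and leaving out any 1 of the 5 other arrays gave 0 calls by limma, with 187 to 450 at an unadjusted p under 0.05. The r between the 2 arrays across probes was -0.07, where probes are not independent replicates.

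No fixed list had a median outside the central 95% of random lists, and for 7 of 13 lists the medians of the 2 arrays had opposite signs. The fibroblast and matrix genes had a median of 0.17 (0.02 and 0.20 on the 2 arrays), with 6 of 7 probes above 0 and DCN at 0.49. The NF-kB targets had -0.11, a sign that neither array showed (0.03 and 0.04), with PLAU at -0.62 and MMP1 at -0.49. Ribosomal proteins, with RPL10A at 0.51 and RPS16 at 0.49, and antigen presentation genes, with B2M at 0.37 and SLA-1 at 0.34, both had a median of 0.09. On the 2 arrays these were -0.05 and 0.21 for ribosomal proteins, the latter at percentile 99.0 of random lists, and 0.17 and -0.10 for antigen presentation. The B2M value rested on 0.89 on array 1 against 0.06 on array 2, and the other 7 B2M probes lay between -0.04 and 0.21. The other 4 SLA-1 probes lay between -0.28 and 0.37. Adjusted over the list alone, 3 translation factor probes, 3 proliferation probes, 1 NF-kB target probe and 1 fibroblast and matrix probe passed. The heat shock genes had a median of 0.08 (HSPH1 at 0.24), the T and NK cell markers -0.08 (CD3D at -0.20), the translation factors -0.07 (EIF4A2 at -0.58 and RACK1 at -0.46), the enterocyte markers -0.06 (FABP1 at 0.38 and EPCAM at -0.35), the inflammatory cytokines 0.05 and the myeloid markers 0.05 (CYBA at -0.24). The interferon-stimulated genes had 0.02 (OAS1 at 0.40 and IFIH1 at 0.30), and the proliferation and oxidative phosphorylation genes 0.01 each (CDC2 at 0.72 and COX6C at 0.35). Medians are of the means over this pair, while gene values are fitted over all 3 pairs. CDC2 had 0.43 and 0.53 on the 2 arrays here, but 1.27 on array 1 of stimulated against normal. OAS1 had 0.92 and 0.11, and its second probe had 0.06.

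The comparison of the stimulated with the normal library is the one that addresses the response to stimulation, and it gave no named gene past the test. The inflammatory cytokine genes had a median of -0.04 over 20 probes of 17 genes, with 6 above 0 and 14 below 0. This median lay at percentile 70.4 of random lists of named probes, so the list was not low among named probes. The members with the largest mean over both arrays were CSF3 at -0.20 and IL1A at 0.35 as fitted. The receptor gene TLR2, which senses bacterial lipoproteins, had 0.43 (SE 0.12, limma adjusted p = 0.14) with 0.35 and 0.51 on the 2 arrays. LYZ had -0.49 (SE 0.12, adjusted p = 0.11), with -0.22 and -0.64, and its second probe had -0.05. The interferon-stimulated gene USP18 had 0.52 (adjusted p = 0.10), resting on 1.16 on array 1 against 0.06 on array 2, and its second probe had -0.26.

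Of 3072 probes 132 were called, 119 above 0 and 13 below 0, none of them named, and 477 had an unadjusted p under 0.05. The repeated grid positions held 82 of them, all above 0, and the 50 elsewhere were 37 above 0 and 13 below 0. Other probes of layout row 1 made up 36 of these 50, which left 14 outside that row, 11 above 0 and 3 below 0. Outside that row the balance turned to mostly below 0 when array 1 of both stimulated pairs was left out. Without array 1 of both stimulated pairs, 593 were called, 357 above 0 and 236 below 0. Fits of the single arrays called 0 with 6 arrays by limma (469 at an unadjusted p under 0.05) and 6 with 9 arrays. In the pair-mean fit only 66 of the 132 had the same sign on both arrays. By size, 1 unnamed probe reached 2-fold on both arrays. Without array 1 of this pair 253 were called, 5 of them named, while leaving out array 2 of this pair, array 2 of stimulated against subtracted, or either array of normal against subtracted gave 0 by limma (110, 242, 333 and 381 at an unadjusted p under 0.05).

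Of 13 lists, 5 had medians of opposite sign on the 2 arrays. The NF-kB targets had a median of 0.11 at percentile 96.9 of random lists, but -0.02 and 0.02 on the single arrays, with NOS2 at 0.34 and no call. The translation factors had -0.17 (-0.11 and -0.35), with EEF1G at -0.29 and EIF4A2 at -0.22. Of the 21 enterocyte probes 18 lay below 0, with a median of -0.11 at percentile 13.5 of random lists, and the second FABP2 probe had -0.74 and EPCAM -0.37. The interferon-stimulated genes had a median of -0.11, with PSMB10 at -0.42, and the antigen presentation genes -0.04, with TAP1 at -0.37 and SLA-1 at -0.41. The latter list had 0.14 on array 1 and -0.26 on array 2, at percentile 1.5 for array 2 alone. B2M made up 8 of its 20 probes, and the random lists did not allow for such repeats. The other 4 SLA-1 probes lay between -0.09 and 0.23. Medians were -0.08 for ribosomal proteins (RPL10 at -0.26), -0.05 for heat shock genes (HSP90AA1 at -0.24), -0.03 for T and NK cell markers (CD3D at -0.35 and CD4 at 0.26) and -0.03 for oxidative phosphorylation (NDUFA4 at 0.24). They were 0.08 for proliferation genes (CDC2 at 0.40, with 1.27 and 0.01 on the 2 arrays), 0.02 for myeloid markers and -0.02 for fibroblast and matrix genes (ANXA2 at -0.20). Adjusted over the list alone, 2 myeloid probes passed, 1 of them above 0, and no member of another list did.

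The direct stimulated against normal value of a probe could be set against the difference of its other 2 comparisons. The r across probes was 0.60 with a slope of 0.41, and without the repeated grid positions r was 0.38. Using only array 1 of each pair, r was 0.03. Using only array 2, r was 0.60 with a slope of 0.74, and without array 1 of both stimulated pairs r was 0.755 with a slope of 0.81. In the last setting a dye bias does not cancel and would enter both sides, so this r may hold some of it. Both second stimulated arrays correlated with the 3 arrays of subtracted cRNA in both channels, which hold no library difference. For stimulated against subtracted r was 0.32, 0.21 and 0.32, and for stimulated against normal 0.27, 0.14 and 0.14. The 2 second stimulated arrays had r = 0.39 with each other.

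**Figure D3:**
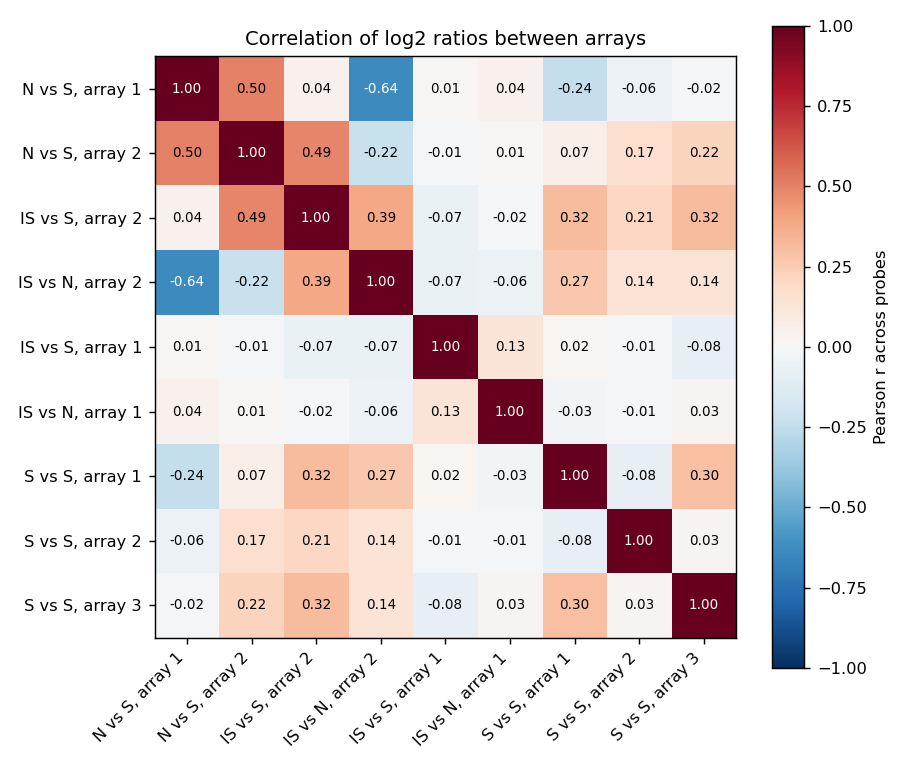
Pearson r across 3072 probes between the log2 ratios of each 2 of the 9 arrays, as coloured cells with the value printed (N normal, IS stimulated, S subtracted). Array 1 of each stimulated pair has r between -0.08 and 0.13 with every other array, while array 2 of stimulated against normal has -0.64 with array 1 of normal against subtracted.

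The 3 arrays with subtracted cRNA in both channels give the level of array error at 3 amounts of cRNA, with 1 array per amount. The SD of the log2 ratio over probes was 0.294 at 2 µg, 0.281 at 500 ng and 0.235 at 200 ng. The share of probes at 2-fold or more was 0.91% (95% Wilson interval 0.63 to 1.31), 0.88% (0.60 to 1.28) and 0.65% (0.42 to 1.00), intervals that treat probes as independent. Named genes furthest from 0 on these arrays were MX1 at 1.01 and ITGB2 at 0.91 for 2 µg, TRA2A at -0.75 for 500 ng, and TRAF5 at 0.60 for 200 ng, values that stand for error alone. An order among the amounts could not be tested without replicate arrays.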

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

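The grouping by grid position and the 4 tests of its explanations were chosen only after the result was seen, while the test of stimulated minus normal was planned. A set of 96 unnamed probes at 4 repeated grid positions, in row 1 and columns 4, 8, 12 and 16 of each of 24 layout blocks, differed between the comparisons. Against the subtracted library these probes had median log2 ratios of -2.09 and -0.98 on the 2 normal arrays, and -0.10 and 0.00 on the 2 stimulated arrays. In the test of the difference, stimulated minus normal, 82 of the 96 were called. Fits of the single arrays called 0 of them with 6 arrays by limma (469 of all probes at an unadjusted p under 0.05) and 5 with 9 arrays. Array 2 of stimulated against normal had a median of 2.03 and array 1 of it -0.05.

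A dye bias of these features is argued against by the arrays with 1 cRNA in both channels, where the largest absolute median was 0.05. A trend across the slide is argued against because the median of normal against subtracted was -1.60 after each print block was centred. Layout row 1 as the whole cause is argued against, since its 288 other probes had a median of -0.19, although on array 2 of stimulated against normal their median of 0.58 also lay apart from the -0.15 outside that row. The annotation names 0 of the 96 probes, so a control feature that differs between the cRNA preparations cannot be told apart from a pig transcript that does, and the difference between stimulated and unstimulated tissue stays open, untested, as a biological explanation.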

How the results depend on the processing

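Counts are given in the order normal against subtracted (140), stimulated against subtracted (7) and stimulated against normal (132). Where a value changed, the cause was not tested unless the setting itself shows it. Array-level fits with a dye term (replicate block) gave 0, 0 and 0 calls by limma on 6 arrays (667, 526 and 469 at an unadjusted p under 0.05) and 129, 4 and 6 on 9 arrays. The replicate number pairs arrays by channel order only, so this is no test of a shared origin. An adjusted p under 0.01 left 40, 0 and 0, and requiring 2-fold left 89, 7 and 74. Median centring, scaling and block centring each took stimulated against subtracted to 0 (506, 407 and 488 unadjusted). Leaving out 1 array in turn gave 0 to 183, 0 to 92 and 0 to 253.

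Of the settings added after seeing the data, the spot median gave 217, 58 and 208. Omission of array 1 of both stimulated pairs gave 465, 680 and 593, and retained 139, 7 and 128 of the calls. Turning the stimulated pairs by channel gave 0, 0 and 0 (17, 81 and 73 unadjusted), as did turning all pairs (80, 320 and 203). Removing the repeated grid positions from the finished calls left 50, 7 and 50, with 13, 0 and 37 above 0 in place of 13, 0 and 119. The fit and the adjustment still held these positions, so whether the other probes pass without them was not tested.

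The counts at 2-fold on both arrays (55, 0 and 1) became 162, 13 and 10 at 1.5-fold and 17, 0 and 0 at 3-fold. Scaling gave 32, 0 and 2, the pair mean alone 113, 24 and 57, and single arrays 105 to 176, 45 to 83 and 48 to 217. The self-hybridised shares became 4.3%, 3.09% and 1.14% at 1.5-fold, and 0.26%, 0.423% and 0.488% at 3-fold, so the order of the amounts at 2-fold is not kept. The closure r ranged from 0.0345 to 0.6 with 1 array per pair and was 0.755 without both first stimulated arrays. Lists outside the random range numbered 1 from the indirect value and 1 to 2 with 1 array for stimulated against subtracted, and 1 after scaling and 1 to 3 with 1 array for stimulated against normal, in place of 0.

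The 12 named calls are 11 genes in normal against subtracted, by 1 probe each, and MDH1 in stimulated against subtracted. All kept their sign and their side of the threshold without both first stimulated arrays and with the spot median. Median centring lost 4 and scaling 10, and each lost all 12 when array 2 of a stimulated pair or either normal against subtracted array was omitted. Without both first stimulated arrays, 4 uncalled values of the probes chosen for naming became calls of the other sign: MMP1 at 0.52 in normal against subtracted and 0.52 in stimulated against subtracted, GP91-PHOX at -0.52 in the latter, and CLCA1 at -0.63 in stimulated against normal. Missing-value filters and the bound on extreme probes removed no probe and so test nothing. Over all named gene values and settings, 1764 kept their sign and side of the threshold, 85 fell short of it, 58 newly passed it and 61 uncalled ones changed sign. Of the list medians, 171 moved by less than the spread between the 2 arrays and 102 by more.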

Other observations

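The lists that read the sign of the ratio were planned, and the other tests, the settings and the genes named in this part were chosen only after the result was seen. Leaving out array 1 of both stimulated pairs leaves 2 arrays that both have the stimulated library in channel 2. A dye bias then does not cancel, is shared by both stimulated comparisons and is not part of the residual behind p. With array 1 of both stimulated pairs left out, a setting chosen after seeing the data in which each stimulated comparison rests on 1 array and is assumed to vary like the others, 32 named probes were called between the stimulated and the normal library. Values above 0 included PSME1, a proteasome activator subunit, at 0.88, TGFB1 at 0.72, the inducible nitric oxide synthase gene NOS2 at 0.67, and TLR2 at 0.47. Below 0 the furthest were both FABP2 probes at -1.31 and -0.85, SPAI-2 at -0.64 by 1 of 3 probes, CLCA1 at -0.63, HSP90AA1 at -0.63 by 1 of 5 probes, and LYZ at -0.61. EPCAM at -0.56 and TAP1 at -0.54 were also called, and T cell markers went both ways, with CD3D at -0.48 and CD4 at 0.47. ITGB2, the common chain of the leukocyte integrins, was called at 0.73, but on arrays with the same cRNA in both channels its probe had 0.91 and -0.63, and that of CD4 had 0.83. Of the 32 probes 5 had a value at least as large as the called one on such an array. The second probes of TGFB1, LYZ and EPCAM, at 0.44, -0.17 and -0.40, were not called.

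Against the subtracted library the same setting called 65 named probes for the stimulated library. Below 0 the furthest genes, each by its lowest probe, were CLCA1 at -2.40, PGK1 at -2.05, CTLA4 at -1.87, PPP1R14B at -1.83 and SPAI-2 at -1.44. PPIA at 1.23, TGFB1 at 0.89 and RPS16 at 0.83 were the furthest above 0, while the second PPIA and TGFB1 probes had 0.39 and 0.11 and were not called. Of the cytokine genes, IL6 had -0.55, CSF3 -0.55, TNF -0.51 and CXCL2 0.43. The CXCL2 value rests on 1 of 3 probes, the others having -0.12 and -0.13, and the second IL6 probe had -0.06. On arrays with the same cRNA in both channels these probes reached -0.53 for IL6, 0.43 for CSF3 and 0.47 for TNF.

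Array 1 of each stimulated pair shared little with its partner, while the 2 first arrays had a rank correlation of 0.22 with each other (r = 0.13, and rank correlation 0.21 on named probes). A ratio turned the wrong way is argued against, since the largest absolute r of either array with its partner was 0.07. Random spot noise on correctly placed values is argued against by the repeated grid positions, whose median was -0.05 on array 1 of stimulated against normal. For array 1 of stimulated against subtracted, the 11 other probes at 2-fold on both normal against subtracted arrays had a median of -0.06 (SE 0.12), signed as there, against 1.79 on its partner. Among 384 orders and reversals of the print axes, the highest absolute rank correlation with the partner was 0.07 for stimulated against normal and 0.05 for stimulated against subtracted, which argues against a simple re-sorting. A candidate explanation that stays open is that spot identities on these arrays are out of register in another way. Spots of 1 probe 2 block rows apart exceeded those of different probes 4 block rows apart by -0.02 in rank correlation for stimulated against normal. The excess was 0.03 for stimulated against subtracted and 0.23 to 0.41 on the other 4 arrays. Spots at both spacings share their place within a block. For stimulated against normal the 2 spacings gave 0.22 and 0.24, spots of 1 probe 8 rows apart 0.23, and neighbouring spots 0.04. For stimulated against subtracted these were 0.30, 0.27, 0.34 and 0.18. A failed hybridisation or a mislabelled array was not tested. The labels give both arrays of a pair the same pools, so no biological explanation was tested.

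The sign of the ratio was the last question. That the first-named library is the numerator may hold, but of the 6 medians of the fibroblast, ribosomal and translation lists against the subtracted library 4 were above 0, which leaves it open. Of the 6 correlations among the other 4 arrays, 3 had the sign of the channel order and all 6 that of the titles. On named probes the counts were 2 and 5. Those among array 2 of each pair have the same expected sign in both orders and cannot tell them apart. The others, with array 1 of normal against subtracted, were -0.64, 0.50 and only 0.04, all with the title sign. On named probes they were -0.07, 0.59 and 0.59. These values argue against ratios that follow the channels as labelled in all pairs. An order with only the stimulated pairs turned was not counted in this way. It would put array 2 of stimulated against subtracted below 0 with both normal against subtracted arrays, where named probes gave 0.59 and 0.76. It would put array 2 of stimulated against normal above 0 with them, where named probes gave -0.07 and 0.12.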
